A study of Mus musculus with 32 samples.

How the data were processed

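Ribosome-bound RNA (TRAP IP) and input RNA were sequenced from cortex of Gprin3-bacTRAP and Colgalt2-bacTRAP mice, in 32 libraries of 10 groups. Per the labels, 15 ng of RNA per sample was amplified with NuGEN Ovation V2 and made into libraries with the TruSeq v2 kit. Per the submitters' processing notes, reads were aligned to mm10 with Subread and assigned to genes with featureCounts (versions not given in the sources used here), and comparisons were made with DESeq2 1.26.0. The deposited files of each library hold gene counts for 24100 features. The authors' deposited comparison tables hold mean signal (baseMean), log2 fold changes with standard errors, and a p-value with its adjusted form for 6 pairwise comparisons. From these tables the log2 fold changes, standard errors and adjusted p values were used for comparison alone. Their 36 columns of values per library, on a transformed log2 scale, were not used here. The 9 features with no symbol, at most 0.0201% of the counts of a library, were left out.

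Samples were grouped by title, line, genotype and RNA type in the labels. The lists, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined, apart from those marked below as chosen later. Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the counts: filterByExpr, TMM factors, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment, with a threshold of 0.05. Each pairwise comparison was fitted on its own groups. The comparison of SOD1*G93A effects between lines was fitted on 12 libraries and that between Gprin3 IP and input on 16, as interaction contrasts. CPM are counts scaled to the library total, with no normalization factor. Positions of the target genes come from the mouse GENCODE annotation of GRCm38 (mm10), and transcript length and GC content from the longest transcript of 21166 genes.

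The 35 gene lists fixed beforehand were markers of layer 5b extratelencephalic (including both driver genes), layer 5 intratelencephalic, layers 2 to 4 and layer 6 neurons, interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, disease-associated microglia, reactive astrocytes, vascular cells and blood. They also covered nuclear oxidative phosphorylation, mitochondrially encoded, cytoplasmic ribosome, mitochondrial ribosome, proteasome, glycolysis, unfolded protein and integrated stress response, heat shock and immediate early genes. The others were ALS, axonal cytoskeleton and transport, injury and regeneration, interferon, cholesterol synthesis, potassium channel, sodium and HCN channel, calcium channel, glutamate receptor, GABA receptor, axon guidance, synaptic vesicle and sex chromosome genes. Lists with at least 5 tested members were tested with camera, two-sided, at a preset correlation of 0.01, adjusted over the lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone.

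Genes were named by rule. Part a took, per comparison, up to 8 genes per direction with the largest fold change among those past the threshold, with a mean of at least 5 CPM in the higher group and, for comparisons of groups, no overlap between libraries. Where fewer than 6 genes passed, the 6 with the smallest p were named as not past the threshold. Part b took up to 3 passing members of a called list in its direction and 1 in the other, or up to 2 of a list not called. Part c was fixed: Sod1, Rpl10a, Gprin3, Colgalt2, Fezf2, Bcl11b, Crym, Gad1, Slc17a7, Aqp4, Gfap, Mbp, Cx3cr1, Xist and Ddx3y. Symbols of predicted genes were excluded from parts a and b. Not every gene so named is printed, and genes named outside the rule are marked where they appear in the closing section.

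Library totals ran from 10865185 to 77228512 counts. Tested on simulated data with the group sizes, depth and dispersion of each comparison, the share of genes with a 2-fold change that was recovered was 69% for Gprin3 IP against input, 19% for Colgalt2 IP against input, 13% for Gprin3 against Colgalt2 IP, 48% and 64% for SOD1*G93A in Gprin3 and Colgalt2 IPs, and 100% for M1 input. It was 16% for the interaction between lines and 66% for that between IP and input. At 4-fold these shares were 100%, 82%, 77%, 90%, 99%, 100%, 79% and 100%, with between 2 and 20 false calls. The changed genes were drawn among those averaging more than 5 CPM, so these shares do not cover genes at lower levels. With a length trend added to simulated SOD1*G93A Gprin3 IPs, 671 false calls arose without a length correction and 6 with it.

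The alternatives were size factors of DESeq2 1.42.0 (RLE), no low-count filter, a mean of at least 5 CPM, DESeq2's Wald test, replicate numbers as a block, thinning to the smallest library, each library left out, joint fits of all 9, 12 or 16 libraries of a set, an input-corrected difference of enrichment, WT littermate IPs in place of baseline IPs, the sequenced read as a covariate, leaving out the 2 Colgalt2 libraries counted from R1, fry, and camera with an estimated correlation. Chosen after seeing the data were a correction for each library's trend on transcript length, on GC content or on baseline IP over input fold, baseline IPs in place of WT littermate IPs, and sex as a covariate (Ddx3y at 1 CPM or more). Counts of 44 pairs of libraries within groups were checked for duplicates, and the chi-square per degree of freedom ran from 6.58 to 175. Figures were drawn with Python 3.11.15.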

Results

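The data were RNA sequencing counts from the cerebral cortex of adult mice aged 8 to 17 weeks, made by translating ribosome affinity purification (TRAP). In a bacTRAP line, a transgene on a bacterial artificial chromosome puts a tagged ribosomal protein L10a under the control of a driver gene. The immunoprecipitate (IP) then holds ribosome-bound mRNA of the driver's cells. Per the labels, the Gprin3 line marked lower and the Colgalt2 line upper layer 5b neurons. Input was RNA of whole primary motor cortex (M1). At baseline there were 2 Gprin3 IPs with 3 inputs and 2 Colgalt2 IPs with 2 inputs. For mice carrying mutant human SOD1*G93A, a model of amyotrophic lateral sclerosis (ALS), and their wild-type (WT) controls, there were 3 SOD1*G93A and 2 WT Gprin3 IPs, 4 SOD1*G93A and 3 WT Colgalt2 IPs, and 6 SOD1*G93A and 5 WT M1 inputs. The 7 Colgalt2 IPs of that second set came from whole cortex per their characteristics, although their source names read M1. The 32 libraries held 10865185 to 77228512 counts each. Levels are given as mean CPM (counts scaled to the library total) ± SD, log2 fold changes as estimate ± SE, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg correction over all genes tested. No label states that replicates were separate animals, so the p values measure spread between samples.

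The targets were checked first, in every group. Gprin3 (chromosome 6, 59347226 to 59426294, mm10), the driver of the lower layer 5b line, was at 44.3 ± 7.64 CPM in baseline Gprin3 IPs, 12.9 ± 1.84 CPM in their inputs, 17 CPM in Colgalt2 IPs and 15.2 CPM in Colgalt2-line inputs. In the second set it was at 30.4 CPM in WT and 45.1 CPM in SOD1*G93A Gprin3 IPs, 29.7 and 31.6 CPM in WT and SOD1*G93A Colgalt2 IPs, and 11.6 and 13.1 CPM in the inputs. Colgalt2 (chromosome 1, 152399830 to 152510695), a collagen galactosyltransferase gene and the other driver, was at 88.2 ± 12.5 CPM in baseline Colgalt2 IPs and 54.9 ± 2.97 CPM in Colgalt2-line inputs, but at 4.2 CPM in Gprin3-line inputs and 5.31 CPM in Gprin3 IPs. It reached 103 and 125 CPM in the WT and SOD1*G93A Colgalt2 IPs and stayed between 3.39 and 7.06 CPM in the other groups of that set. Sod1 (chromosome 16, 90220754 to 90226329), which encodes cytosolic superoxide dismutase, was at 718 ± 23.7 CPM in SOD1*G93A and 322 ± 2.12 CPM in WT Gprin3 IPs, 412 ± 37.1 and 262 ± 60.7 CPM in Colgalt2 IPs, and 399 ± 33.9 and 342 ± 32.3 CPM in M1 input. At baseline Sod1 was already at 635 ± 233 CPM in Gprin3 IPs, 484 CPM in their inputs, 242 CPM in Colgalt2 IPs and 438 CPM in Colgalt2-line inputs. Reads of the human transgene were counted only as far as they aligned to the mouse gene. Rpl10a (chromosome 17, 28328471 to 28331033), whose protein carries the tag, was at 30.4, 23.5, 17.9 and 27 CPM in the baseline Gprin3 IPs, their inputs, Colgalt2 IPs and their inputs. It was at 16.2 and 29.5 CPM in WT and SOD1*G93A Gprin3 IPs, 28.4 and 36.4 CPM in Colgalt2 IPs, and 18.6 and 14.1 CPM in M1 input.

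**Figure D1:**
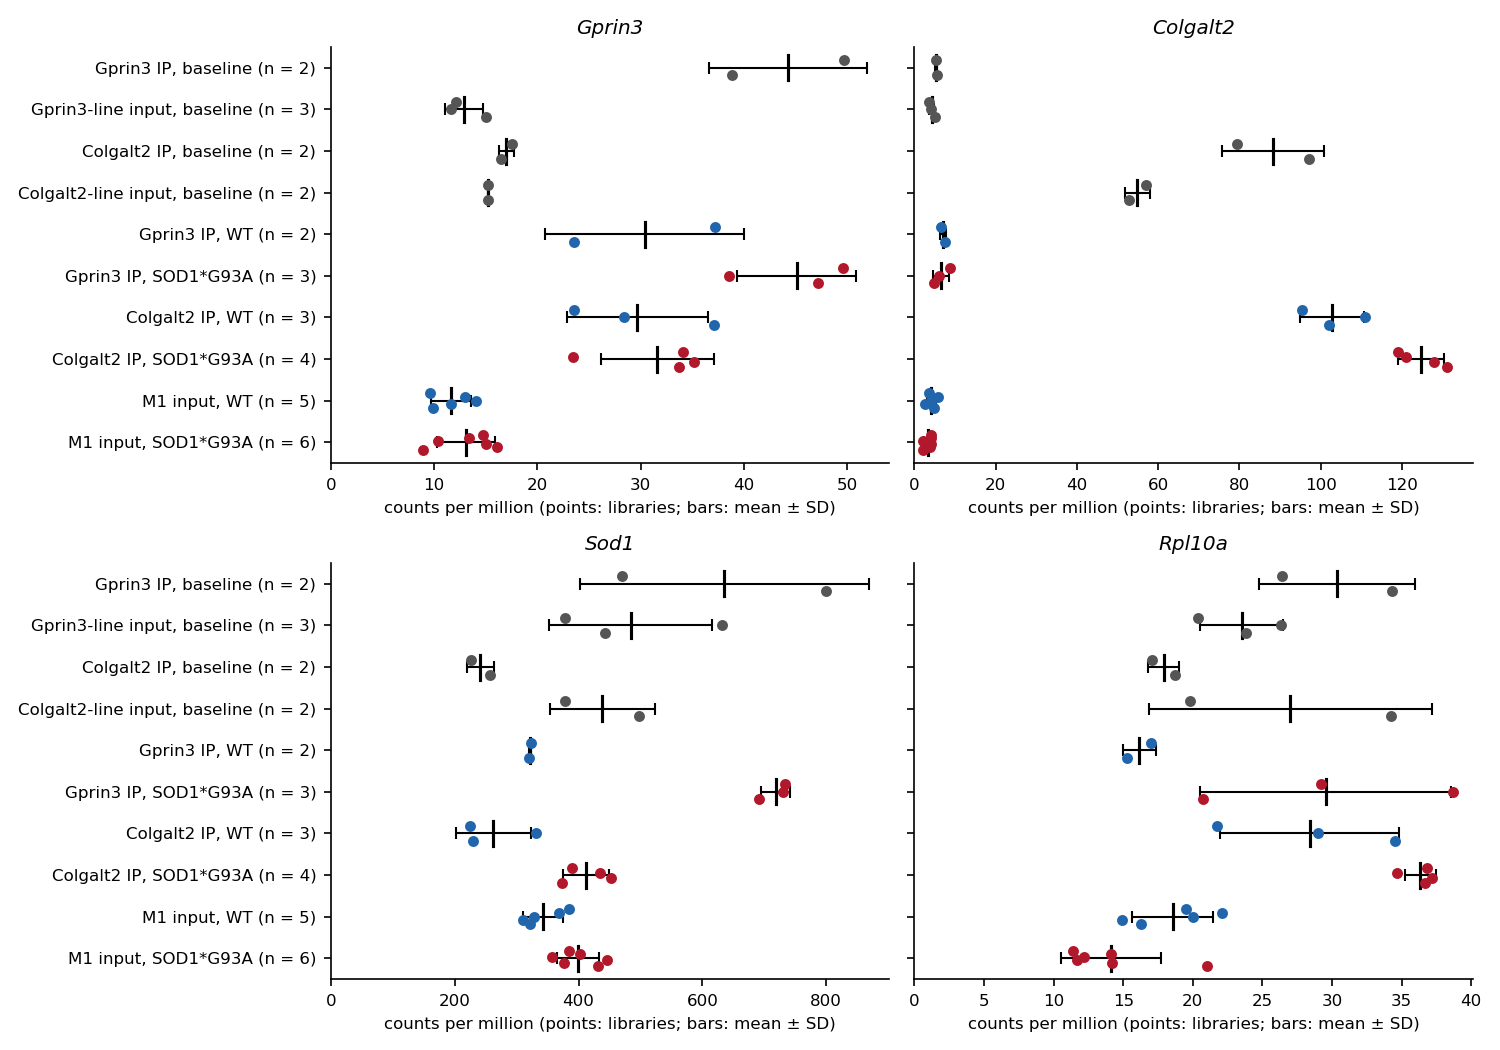
CPM of Gprin3, Colgalt2, Sod1 and Rpl10a in each library (points) of the 10 groups, with group mean and SD as bars. Colgalt2 lies near 54.9 CPM in whole M1 tissue of the Colgalt2 line against 4.2 CPM in that of the Gprin3 line, and Sod1 lies at 718 CPM in SOD1*G93A Gprin3 IPs against 322 CPM in WT.

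In the Gprin3 line at baseline, ribosome-bound RNA (n = 2) held more transcripts of layer 5b neurons and of their axons, and far less glial RNA, than M1 input (n = 3). Of 20 layer 5b extratelencephalic marker genes, 18 rose and none fell, also when adjusted over the list alone. They included Fezf2, the transcription factor that specifies subcerebral projection neurons (117 ± 27.8 against 42.9 ± 8.49 CPM, log2 fold change 1.67 ± 0.19, adjusted p = 7.02e-05). Crym, which encodes a thyroid hormone binding protein of deep layer neurons, rose by 1.44 ± 0.17 on the log2 scale. The neurofilament genes Nefm and Nefh rose by 1.96 ± 0.14 and 1.84 ± 0.15, and Gprin3 itself rose by 2 ± 0.22 (adjusted p = 5.02e-05). All 14 oligodendrocyte and 13 of 14 astrocyte markers fell, both counts unchanged when adjusted over the list alone. Opalin, a myelin protein gene, fell by 5.17 ± 0.44, Mbp (myelin basic protein) fell by 1.61 ± 0.16, and Gfap, the astrocyte intermediate filament gene, fell by 3.58 ± 0.45. The astrocyte marker S100b rose by 1.18 ± 0.15. In camera's set test, the adjusted p was 8.59e-24 for layer 5b, 5.87e-26 for oligodendrocyte and 1.45e-13 for astrocyte markers (adjusted p = 0.108, 0.117 and 0.117 with an estimated correlation).

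Some interneuron genes were among the largest changes in the same IPs. Sst, the neuropeptide somatostatin of a class of inhibitory interneurons, rose by 2.95 ± 0.17 on the log2 scale (661 ± 26.3 against 99.3 ± 20.2 CPM, adjusted p = 5.08e-07), and Htr3a, an ionotropic serotonin receptor gene, rose by 3.24 ± 0.46. Of 17 interneuron markers 7 rose and 4 fell (9 and 4 adjusted over the list alone). Tac1, which encodes the precursor of substance P, fell by 2.43 ± 0.31. Gad1, which encodes a GABA-synthesizing enzyme, was at 118 ± 15.2 against 129 ± 27.3 CPM (adjusted p = 0.748). Bcl11b, a partner of Fezf2, rose by 0.74 ± 0.14 and Slc17a7, the vesicular glutamate transporter, by 0.71 ± 0.15. Among the largest rises were those of Ubr3, a ubiquitin ligase gene (4.60 ± 0.24, from 264 to 5480 CPM), and Atg7, an autophagy gene (4.23 ± 0.21). Among the largest falls were those of C1qc, a complement gene of microglia (-5.99 ± 0.88), and Neat1, a nuclear long noncoding RNA (-5.20 ± 0.66). By the naming rule, the genes named for the largest changes in this and every other comparison of groups had no overlap between the libraries of both groups.

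Genes of energy metabolism rose together in the Gprin3 IPs. Of 76 nuclear genes of oxidative phosphorylation, 70 rose and 1 fell (72 and 1 adjusted over the list alone), with a median log2 fold change of 0.91 (adjusted p = 2.47e-27, and 0.248 with an estimated correlation). Cox5a, a cytochrome oxidase subunit gene, rose by 1.25 ± 0.18. Mitochondrial ribosome genes rose in 40 of 77 cases (48 over the list alone), proteasome genes in 23 of 37 (29), glycolysis genes in 13 of 16 (13, with Aldoc lower) and heat shock genes in 11 of 18 (12). Axonal cytoskeleton and transport genes rose in 16 of 30 (18) and synaptic vesicle genes in 14 of 26 (15). The camera calls of these 6 lists ran from an adjusted p of 6.26e-11 to 0.000679 (0.117 to 0.361 with an estimated correlation). Microglia (12 of 15, 13 over the list alone), oligodendrocyte precursor (7 of 9, 7, with Cspg4 higher), vascular (7 of 15, 13), disease-associated microglia (6 of 12, 7), layer 6 (6 of 11, 6, with Syt6 higher) and potassium channel genes (29 of 79, 31) fell (adjusted p from 9.44e-08 to 0.0302, and 0.117 to 0.245 with an estimated correlation). The potassium channel call was lost without IP 2 (adjusted p = 0.0795) or input 3 (0.0568). The interneuron list was called higher (adjusted p = 0.000679, and 0.137 with an estimated correlation).

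Lists that camera did not call in the Gprin3 line held members that rose or fell, given as rose/fell over all genes tested. These were layer 5 intratelencephalic (2/5 of 8), layers 2 to 4 (2/2 of 12), reactive astrocyte (1/2 of 10), cytoplasmic ribosome (4/1 of 76), unfolded protein and integrated stress response (4/1 of 22), immediate early (0/3 of 20), ALS (12/7 of 36), injury and regeneration (3/5 of 16), interferon (3/2 of 20) and cholesterol synthesis genes (2/2 of 22). Sodium and HCN channel (5/2 of 15), calcium channel (2/5 of 23), glutamate receptor (7/4 of 25), GABA receptor (3/4 of 16), axon guidance (9/13 of 64) and sex chromosome genes (0/1 of 5) were not called either. Of 4 blood genes 2 fell, a list too short for the set test, and no mitochondrially encoded gene was in the count tables. Altogether 4244 of 14534 genes tested changed, 2019 higher and 2225 lower. That count was 2284 without input 1, 2693 without input 2 and 2568 without input 3. Of the named genes, 90 of the 114 past the threshold stayed past it whichever library was left out.

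**Figure D2:**
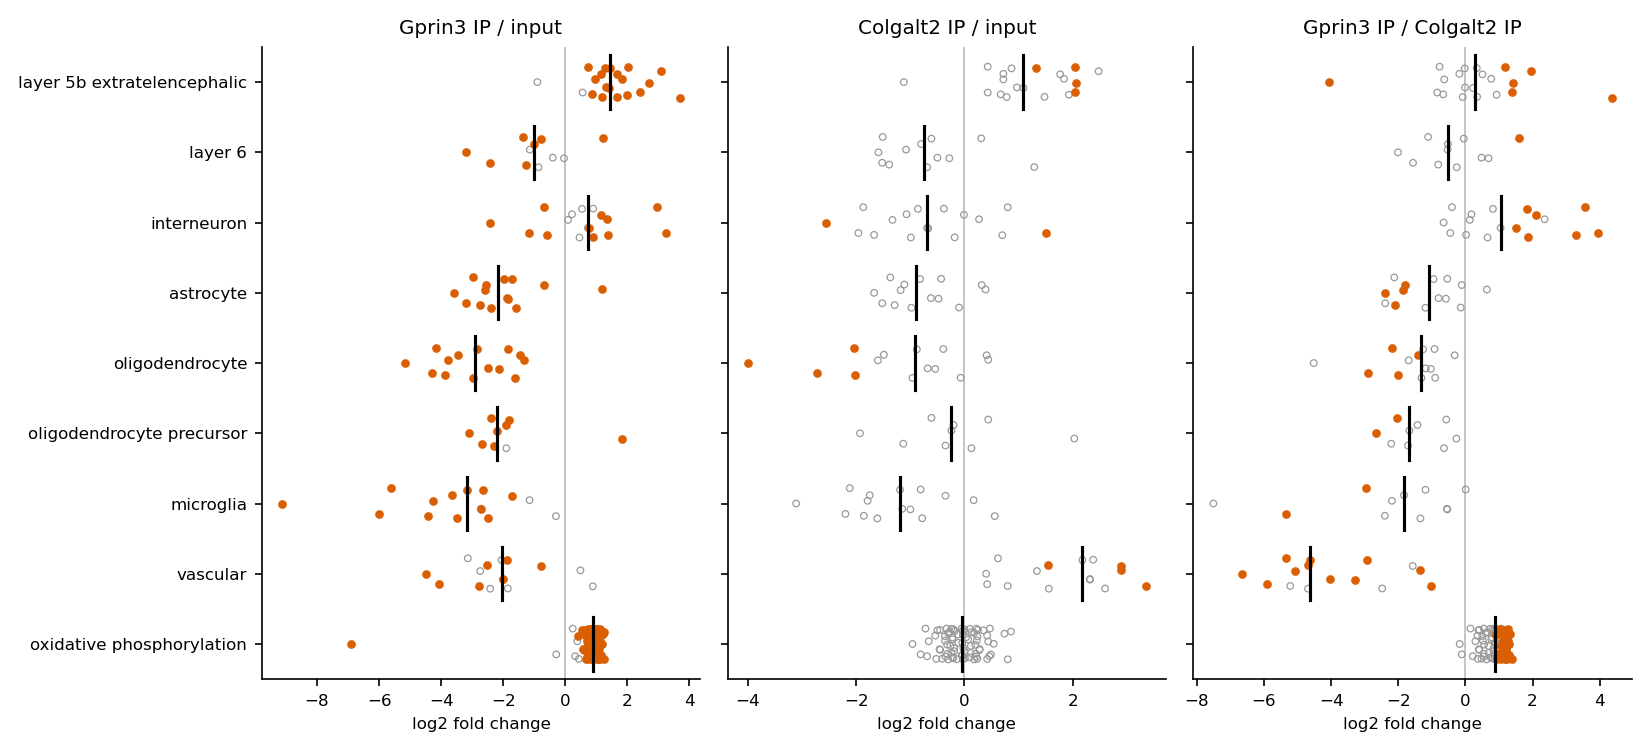
Log2 fold changes of the members of 9 gene lists (points) in baseline Gprin3 IP over input, Colgalt2 IP over input and Gprin3 IP over Colgalt2 IP, with filled points for adjusted p below 0.05 and a bar at the list median. Layer 5b markers lie above 0 in both lines, and vascular markers lie below 0 in the Gprin3 line and above 0 in the Colgalt2 line.

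In the Colgalt2 line, IPs (n = 2) again held more layer 5b and axonal transcripts than input (n = 2), but they also held vascular RNA. Of 19 layer 5b markers 4 rose (14 adjusted over the list alone), among them Nefh (192 ± 35 against 56 ± 4.94 CPM, log2 fold change 2.04 ± 0.22, adjusted p = 0.0388) and Vat1l, a marker of large layer 5 neurons (2.06 ± 0.37). Fezf2 was at 204 ± 140 against 45.8 ± 0.619 CPM (2.48 ± 0.52, adjusted p = 0.0541), and the driver Colgalt2 at 88.3 against 54.9 CPM (0.97 ± 0.24, adjusted p = 0.0722). Axonal cytoskeleton and transport genes rose in 10 of 30 cases (21 over the list alone), led by Dync1h1, the heavy chain of the dynein motor (4.26 ± 0.55). Among 15 vascular markers 4 rose (9 over the list alone), such as Flt1, a VEGF receptor of endothelium (3.35 ± 0.49), and Ly6c1 (2.89 ± 0.43). Irf4, a transcription factor of immune cells, rose by 4.77 ± 0.66, from 0.402 to 9.33 CPM, while Ubr3 and Atg7 rose by 4.08 ± 0.53 and 3.39 ± 0.65. Opalin fell by 4.01 ± 0.56, and Npy, a neuropeptide of interneurons, by 2.56 ± 0.42.

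The set test called 19 lists in the Colgalt2 line. Of these calls 8 were lost when some library was left out, in fits that leave 1 sample in a group. Layer 5b (adjusted p = 1.72e-09, and 0.552 with an estimated correlation), axonal (7.91e-16, and 0.357) and vascular lists (3.88e-07, and 0.574) were higher. Oligodendrocyte (4 of 14 fell, 8 over the list alone, adjusted p = 6.6e-07), cytoplasmic ribosome (2 of 75, 34 over the list alone, 3.88e-17), astrocyte (0 of 14, 2, 0.00324) and microglia lists (0 of 15, 4, 0.000465) were lower (each 0.574 with an estimated correlation). Mbp was not lower, at 258 ± 129 CPM in IPs and 229 ± 46.9 CPM in input (0.41 ± 0.32, adjusted p = 0.471). The summed CPM of glial markers was 3480 and 2180 in Colgalt2 IPs 1 and 2 and 3740 to 4980 in their inputs, against 1120 to 1140 in Gprin3 IPs. These 2 IPs were unlike each other, with Snap25 of the synaptic vesicle list at 8890 and 35300 CPM. Oxidative phosphorylation genes, with 0 of 76 called and a median of -0.04, were not called here (adjusted p = 0.562). Altogether 378 of 14247 genes changed, 249 higher and 129 lower, each with an adjusted p between 0.0388 and 0.05, and 3595 had an unadjusted p under 0.05. None of the 43 named genes stayed past the threshold under every left-out library. The count was 1 without input 1, 11 without input 2, 7206 without IP 1 and 4923 without IP 2. With the trend of fold change on transcript length taken out no gene passed, with GC content taken out 83 did, and with DESeq2 1871 did.

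Set directly against each other, the baseline IPs of the 2 lines differed in interneuron, vascular and some layer 5b genes. Sst was at 661 ± 26.3 CPM in Gprin3 IPs (n = 2) and 42.3 ± 12.8 CPM in Colgalt2 IPs (n = 2), a log2 difference of 3.95 ± 0.31 (adjusted p = 6.37e-05). Calb1, a calcium buffer gene, was higher by 2.83 ± 0.32, and Dlx5, a transcription factor of inhibitory neurons, by 3.13 ± 0.48. Of 17 interneuron markers 7 were higher and none lower (10 and 1 adjusted over the list alone, camera adjusted p = 1.18e-08, and 0.572 with an estimated correlation). Not every marker was higher. Gad1 was at 118 ± 15.2 against 187 ± 35.3 CPM (-0.65 ± 0.26, adjusted p = 0.153), and Vip at 10.7 against 10.5 CPM. Of 15 vascular markers 11 were lower in Gprin3 IPs (14 over the list alone, adjusted p = 1.89e-15, and 0.572 with an estimated correlation), Flt1 by -5.34 ± 0.71. Colgalt2 was lower by -4.06 ± 0.34 (adjusted p = 6.6e-05) and Gprin3 higher by 1.39 ± 0.33 (adjusted p = 0.0243, and 0.228 and 0.0535 without Gprin3 IP 1 or 2), while Fezf2 was at 117 against 204 CPM (adjusted p = 0.235). Of 20 layer 5b markers 5 were higher and 1 lower (6 and 1 over the list alone), a list camera did not call (adjusted p = 0.206). Dync1h1 and Bsn, a scaffold protein gene of the presynaptic active zone, were lower in Gprin3 IPs by -3.08 ± 0.43 and -2.69 ± 0.29. Xist, a transcript of the inactive X chromosome, was at 0.718 ± 0.598 CPM in Gprin3 and 18.8 ± 3.58 CPM in Colgalt2 IPs (-4.69 ± 0.66, adjusted p = 0.0018). Ddx3y of the Y chromosome was at 30.3 and 39.1 CPM (adjusted p = 0.584). The nuclear RNA Malat1 was at 574 and 1660 CPM, and glial markers summed to 1120 to 1140 and 2180 to 3480 CPM. Sex and whole-tissue RNA may thus contribute to these differences, which was not tested.

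Oxidative phosphorylation genes were higher in Gprin3 than Colgalt2 IPs in 28 of 75 cases (53 over the list alone, median 0.88, adjusted p = 8.32e-24), and cytoplasmic ribosome genes in 10 of 76 (27 over the list alone, adjusted p = 3.83e-15). Oligodendrocyte (4 of 13, 8 over the list alone) and astrocyte markers (4 of 14, 6) were lower, with adjusted p = 2.07e-07 and 0.000311, the astrocyte call being lost without Colgalt2 IP 1 (adjusted p = 0.0532). With an estimated correlation the adjusted p of these 4 lists was also 0.572. Across genes, which are not independent replicates, the difference ran against transcript length (Spearman -0.39). In all, 909 of 13611 genes differed, 303 higher and 606 lower, and 307 did with the length trend taken out. The count was 137 without Gprin3 IP 1, 328 without Gprin3 IP 2 and 1705 without Colgalt2 IP 2. Still, 22 of 71 named genes, Sst, Colgalt2, Flt1, Calb1, Dync1h1 and Bsn among them, stayed past the threshold under every left-out library. Between the WT IPs of the second set, which differ in line and in tissue, 1927 genes differed. Of the 295 shared with the baseline calls 250 had the same sign.

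In Gprin3 IPs, SOD1*G93A (n = 3) came with more mitochondrial and ribosomal transcripts, less glial RNA, and less of several long neuronal transcripts than WT (n = 2). Sod1 was higher by 1.16 ± 0.11 on the log2 scale, 2.23-fold (adjusted p = 0.000264), in all 3 SOD1*G93A libraries. Of 75 oxidative phosphorylation genes 38 rose and none fell (66 adjusted over the list alone, median 0.57, camera adjusted p = 1.18e-27, and 0.297 with an estimated correlation). Atp5c1, a subunit gene of ATP synthase, rose by 0.99 ± 0.13. Cytoplasmic ribosome (14 of 75, 24 over the list alone), mitochondrial ribosome (10 of 77, 21) and proteasome genes (5 of 38, 13) rose as well (adjusted p = 1e-12, 7.45e-12 and 6.28e-06, and 0.419, 0.297 and 0.297 with an estimated correlation). Mbp fell by 1.73 ± 0.15, from 191 ± 19.4 to 57.7 ± 5 CPM, a level close to the 63.8 CPM of the baseline Gprin3 IPs. Oligodendrocyte (9 of 14, 11 over the list alone), astrocyte (6 of 14, 11) and oligodendrocyte precursor markers (3 of 9, 6) fell (adjusted p = 1.78e-14, 4.49e-08 and 0.000111, and 0.297 with an estimated correlation). Microglia (1 of 13, 3 over the list alone) and vascular markers (0 of 11, 3) were called lower too (adjusted p = 0.00118 and 0.00331, and 0.298 and 0.297 with an estimated correlation). So was the list of disease-associated microglia (1 of 11, 2 over the list alone, adjusted p = 0.0495, and 0.323 with an estimated correlation), except without WT IP 2 (0.1) or SOD1*G93A IP 1 (0.054) or 3 (0.0676). The summed CPM of glial markers was 1000 to 1010 in the SOD1*G93A libraries, 2220 to 3180 in the WT libraries and 1120 to 1140 at baseline.

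Genes of the axon and of the active zone were among those that fell in the SOD1*G93A Gprin3 IPs. Dync1h1 fell by 2.49 ± 0.19 (1510 ± 160 to 273 ± 85.7 CPM, adjusted p = 0.000102), and the active zone genes Bsn and Pclo fell by 2.35 ± 0.14 and 2.15 ± 0.13 (both adjusted p = 3.69e-05). Bsn and Pclo were at 168 and 198 CPM in SOD1*G93A and at 850 and 880 CPM in WT IPs. The baseline Gprin3 IPs held Dync1h1 at 344 ± 8.5, Bsn at 160 ± 13.1 and Pclo at 308 ± 90.2 CPM, nearer to the SOD1*G93A than to the WT levels. These falls thus depend on which WT reference is used. The synaptic vesicle list that holds Bsn and Pclo was not called (2 of 26 higher and 3 lower, 4 and 3 over the list alone, adjusted p = 0.0611). Of 30 axonal cytoskeleton and transport genes 12 fell (14 over the list alone, adjusted p = 2.28e-07, and 0.323 with an estimated correlation), Ank3 of the axon initial segment by -1.17 ± 0.14, while Gap43, a growth cone gene, rose by 0.81 ± 0.14 (adjusted p = 0.00841, and 0.155 without WT IP 2). Axon guidance (11 of 61, 14 over the list alone), calcium channel (6 of 22, 7) and glutamate receptor genes (2 of 24, 7) fell (adjusted p = 1.98e-06, 0.00331 and 0.00612, and 0.297, 0.359 and 0.359 with an estimated correlation). Of 36 ALS genes 4 rose, Sod1 among them, and 5 fell (5 and 9 over the list alone), including Unc13a, a synaptic vesicle priming gene (-1.29 ± 0.12), and the receptor gene Erbb4 (-2.03 ± 0.19). Erbb4 was at 34.5 CPM in SOD1*G93A, 141 CPM in WT and 33.6 CPM in baseline Gprin3 IPs. The ALS list was called lower (adjusted p = 0.0476, and 0.297 with an estimated correlation), but not without WT IP 1 (0.0803) or SOD1*G93A IP 1 (0.054), 2 (0.116) or 3 (0.0754). The layer 5b list was called higher (2 of 20, Tox and Ldb2, and 2 over the list alone, adjusted p = 0.00759, and 0.535 with an estimated correlation), but not without SOD1*G93A IP 1 (0.0635). Markers of layers 2 to 4 were called lower (3 of 12, Cux2, Rasgrf2 and Cux1, and 5 over the list alone with 2 higher, adjusted p = 0.00331, and 0.297 with an estimated correlation). Fezf2 was at 127 ± 23.2 against 86.8 ± 11.9 CPM (adjusted p = 0.12) and Gprin3 at 45.2 against 30.4 CPM (adjusted p = 0.211). Potassium channel genes fell in 8 of 72 cases (15 over the list alone, adjusted p = 0.0047, and 0.419 with an estimated correlation), a call lost without SOD1*G93A IP 2 (adjusted p = 0.0547).

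The genes that rose in SOD1*G93A Gprin3 IPs had a median transcript length of 2133 nucleotides and those that fell one of 7242. Fold change ran against length across genes (Spearman -0.39). Of 13733 genes tested 1118 changed, 401 higher and 717 lower. With the length trend taken out 531 did, 262 higher and 269 lower. The median log2 fold change of the oxidative phosphorylation list was then 0.13, with 59 of 75 members above 0. Grin2b, an NMDA receptor gene that fell by 1.10 ± 0.14, stood at 0.19. The count of genes was 299 without WT IP 1, 141 without WT IP 2 and 711 without SOD1*G93A IP 3. Ddx3y, a gene of the Y chromosome, was detected at 1 CPM or more in WT IP 2 but not in WT IP 1 or the 3 SOD1*G93A IPs, so sex also differs between these groups. Still, 12 of 79 named genes, among them Sod1, Mbp, Dync1h1, Bsn, Pclo, Unc13a, Erbb4 and Atp5c1, stayed past the threshold under every left-out library. With the 2 baseline Gprin3 IPs in place of the WT IPs of the same set, 64 genes changed, of which 12 were shared and 10 had the same sign.

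**Figure D3:**
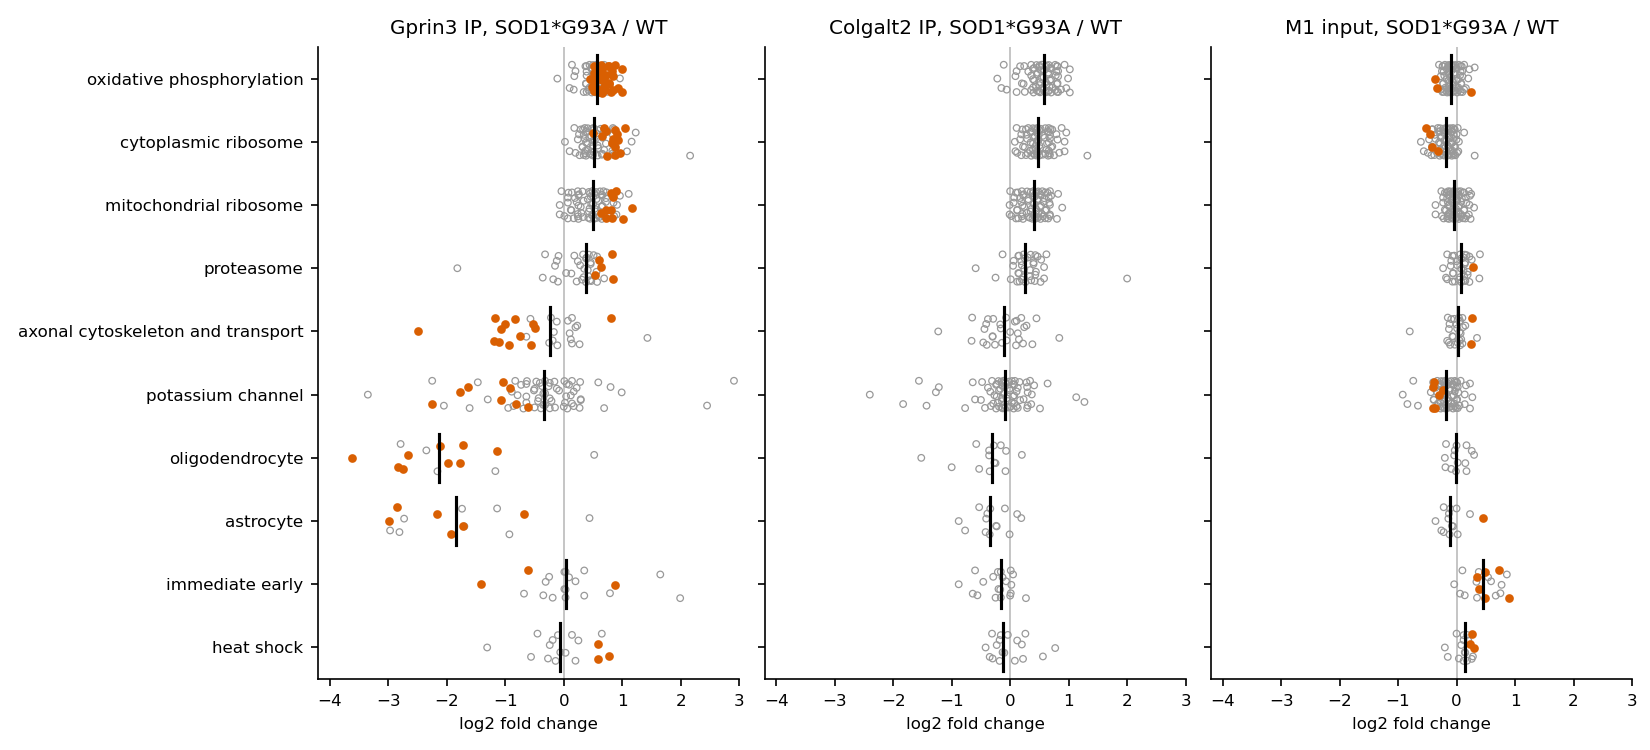
Log2 fold changes of the members of 10 gene lists (points) in SOD1*G93A over WT Gprin3 IPs, Colgalt2 IPs and M1 input, with filled points for adjusted p below 0.05 and a bar at the list median. The oxidative phosphorylation median is 0.57 in both IPs and -0.09 in input.

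In Colgalt2 IPs, no single gene passed the test between SOD1*G93A (n = 4) and WT (n = 3), but the same mitochondrial and ribosomal lists were higher. The 6 smallest p values, none past the threshold (adjusted p = 0.234 each), belonged to Rps14, a small ribosomal subunit gene (1.32 ± 0.23), and to 5 oxidative phosphorylation genes, Atp5e (1.03 ± 0.18), Ndufa4 (0.82 ± 0.15), Ndufb8 (0.99 ± 0.19), Atp5l (1.02 ± 0.20) and Cox7a2 (0.79 ± 0.16). The oxidative phosphorylation list had a median log2 difference of 0.57, with 71 of 75 members above 0, 0 called over all genes and 53 adjusted over the list alone (camera adjusted p = 4.76e-53, and 0.148 with an estimated correlation). Cytoplasmic ribosome (0 of 75, 8 over the list alone), mitochondrial ribosome (0 of 77, 0) and proteasome lists (0 of 38, 0) were higher too (adjusted p = 9.27e-29, 4.94e-20 and 1.41e-09, and 0.148, 0.148 and 0.366 with an estimated correlation). Another 6 lists were called lower with no member called over all genes, and 1 over the lists alone, an interneuron marker. They were oligodendrocyte, oligodendrocyte precursor and axon guidance (adjusted p = 0.00724 each), interneuron (0.00868), layers 2 to 4 (0.0164) and immediate early genes (0.0344), with 0.452 to 0.679 with an estimated correlation. Each lost its call without at least 1 library. Without WT IP 1 the adjusted p was 0.259 for oligodendrocyte, 0.173 for oligodendrocyte precursor, 0.419 for axon guidance, 0.0702 for interneuron and 0.0685 for layers 2 to 4 genes. Without WT IP 3 it was 0.105 for oligodendrocyte, 0.0615 for layers 2 to 4 and 0.46 for immediate early genes. Without SOD1*G93A IP 1, 2 or 3 the lost calls were those of oligodendrocyte (0.051), immediate early (0.255) and axon guidance genes (0.0567). Without SOD1*G93A IP 4 they were layers 2 to 4 (0.111), interneuron (0.0806), oligodendrocyte (0.141), oligodendrocyte precursor (0.0552) and immediate early genes (0.155). Sod1 was at 412 ± 37.1 against 262 ± 60.3 CPM (0.65 ± 0.17, adjusted p = 0.387), Mbp at 238 ± 59.5 against 290 ± 127 CPM and Fezf2 at 410 ± 20.4 against 371 ± 126 CPM. Of 14792 genes tested, edgeR called 0, with 1072 at an unadjusted p under 0.05, DESeq2 called 74 (71 higher), and edgeR called 6 without WT IP 3. Fold change again ran against transcript length (Spearman -0.36), and the oxidative phosphorylation median was 0.16 with that trend taken out. Malat1, a nuclear long noncoding RNA, was at 3970, 1140 and 521 CPM in the WT libraries, and at 2360 CPM in SOD1*G93A IP 2 against 361 to 536 in the other 3. The summed CPM of glial markers was 3480 in WT IP 1, 1630 and 2000 in the other WT libraries and 1440 to 2250 in SOD1*G93A. The oxidative phosphorylation median was 0.49 without WT IP 1 and 0.49 to 0.66 over all left-out libraries. Xist, a transcript of the inactive X chromosome, was at 352 and 164 CPM in WT IPs 1 and 2 and at 138 CPM in SOD1*G93A IP 2, against 0 to 3.54 CPM in the other 4, while Ddx3y was detected in all 7. The sexes can thus contribute unevenly to these groups.

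**Figure D4:**
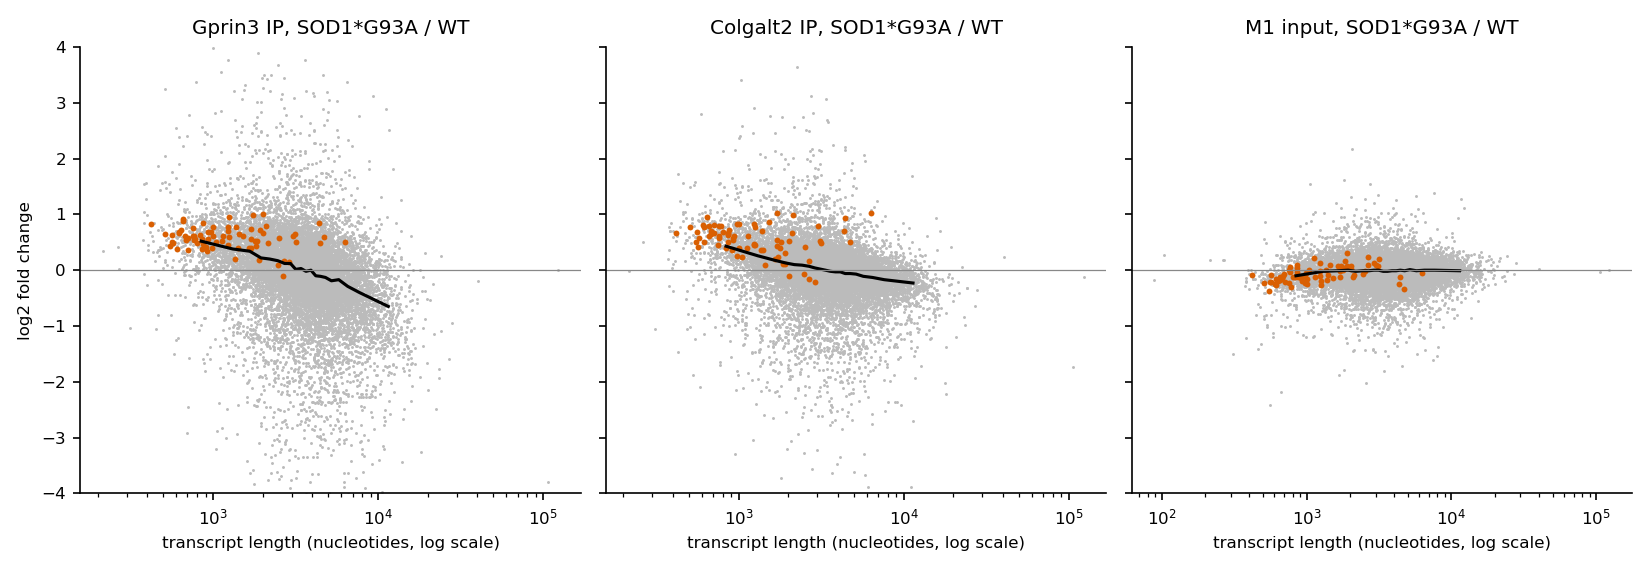
Log2 fold change of every tested gene (grey) against transcript length on a log axis for SOD1*G93A over WT in Gprin3 IPs, Colgalt2 IPs and M1 input, with oxidative phosphorylation genes in orange and the median of 20 length bins as a line. The rank correlation across genes is -0.39, -0.36 and 0.04.

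In whole M1 tissue, SOD1*G93A (n = 6) came with more immediate early and heat shock transcripts than WT (n = 5), and with a rise of the growth factor gene Vegfd. Vegfd (chromosome X), which encodes a ligand of VEGF receptors, was at 7.62 ± 2.36 CPM in all 6 SOD1*G93A inputs above 1.74 ± 0.543 CPM in WT, a log2 fold change of 2.18 ± 0.24 (adjusted p = 9.63e-06). Of 20 immediate early genes 6 rose and none fell (15 adjusted over the list alone, median 0.45, camera adjusted p = 3.47e-15, and 0.144 with an estimated correlation), among them the activity-dependent transcription factor genes Fos (31.4 ± 5.09 against 17.4 ± 5.78 CPM, 0.89 ± 0.19, adjusted p = 0.0195) and Nr4a3 (0.49 ± 0.09). The call of Fos was lost without WT input 3 (adjusted p = 0.0576) or 5 (0.058) or SOD1*G93A input 1 (0.0534) or 2 (0.0585). Of 18 heat shock genes 3 rose (8 over the list alone, adjusted p = 1.12e-05, and 0.144 with an estimated correlation), such as the chaperone gene Hspa8 (0.29 ± 0.05). Klf11, a transcription factor gene, rose by 1.01 ± 0.18, Nectin3, an adhesion molecule gene, by 0.60 ± 0.10 and Tardbp, which encodes the ALS protein TDP-43, by 0.30 ± 0.06. The metallothionein gene Mt2 fell by 0.82 ± 0.12, Hif3a, a hypoxia-inducible factor gene, by 0.81 ± 0.17 and the neuropeptide gene Cck by 0.36 ± 0.06. Sod1 rose by 0.26 ± 0.07 (adjusted p = 0.0255), but not past the threshold without WT input 3 (0.0584), 4 (0.0686) or 5 (0.081) or SOD1*G93A input 1 (0.05) or 4 (0.0852).

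Potassium channel genes fell in M1 input in 6 of 77 cases (14 over the list alone, adjusted p = 2.93e-06), calcium channel genes in 2 of 23 (2, adjusted p = 0.000408) and cytoplasmic ribosome genes in 4 of 75 (5, adjusted p = 1.23e-07), with an adjusted p = 0.144, 0.144 and 0.373 with an estimated correlation. Of 18 interneuron markers 1 rose and 1 fell (2 and 5 over the list alone, adjusted p = 0.00342, and 0.144 with an estimated correlation). Oligodendrocyte (0 of 14 called, median -0.01) and astrocyte markers (Sox9 higher, 0 lower of 14) were not called, with adjusted p = 0.929 and 0.292. Microglia (0 of 15, 0 over the list alone) and vascular markers (0 of 14, 0) were called lower (adjusted p = 0.0193 each, and 0.373 with an estimated correlation). The microglia call was lost without WT input 5 (0.0916) or SOD1*G93A input 2 (0.0651), and the vascular call without WT input 3 (0.127) or 5 (0.0501). The glutamate receptor list was drawn by gene symbol, which also took in Grina. That gene was the member called lower (-0.27 ± 0.07), while the NMDA receptor gene Grin2b was called higher (0.26 ± 0.07). As lists, glutamate receptor (1 of 25 lower and 1 higher, 4 and 1 over the list alone, 0.0193), GABA receptor (0 of 15, 1, 0.0272) and axon guidance genes (1 of 63, 1, 0.0181) were called lower and proteasome genes (1 of 37, 2, 0.02) higher, with 0.144, 0.373, 0.373 and 0.373 with an estimated correlation. These calls were lost too, for glutamate receptors without WT input 4 (0.0557) or 5 (0.0501), for GABA receptors without WT input 3 (0.0819), 4 (0.0507) or 5 (0.0501) or SOD1*G93A input 2 (0.105), for axon guidance without WT input 3 (0.0506), and for the proteasome without WT input 3 (0.0866) or SOD1*G93A input 3 (0.0738). Of 76 oxidative phosphorylation genes 1 rose and 2 fell (3 and 7 over the list alone, median -0.09, adjusted p = 0.0193, and 0.639 with an estimated correlation). This call was lost without WT input 1 (adjusted p = 0.333), WT input 2 (0.372) or SOD1*G93A input 2 (0.116). In all 482 of 14331 genes changed, 298 higher and 184 lower, of which 12 changed at least 2-fold. The count was 267 without WT input 3, 180 without WT input 5, 200, 316, 277 and 232 without SOD1*G93A inputs 1, 2, 3 and 4, and 262 with the GC trend taken out. Of the named genes 20 of 51, Vegfd, Klf11, Nr4a3, Hspa8, Mt2 and Cck among them, stayed past the threshold under every left-out library. Ddx3y was detected at 1 CPM or more in 1 of 6 SOD1*G93A and 2 of 5 WT inputs. With that split as a covariate 334 genes changed.

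**Figure D5:**
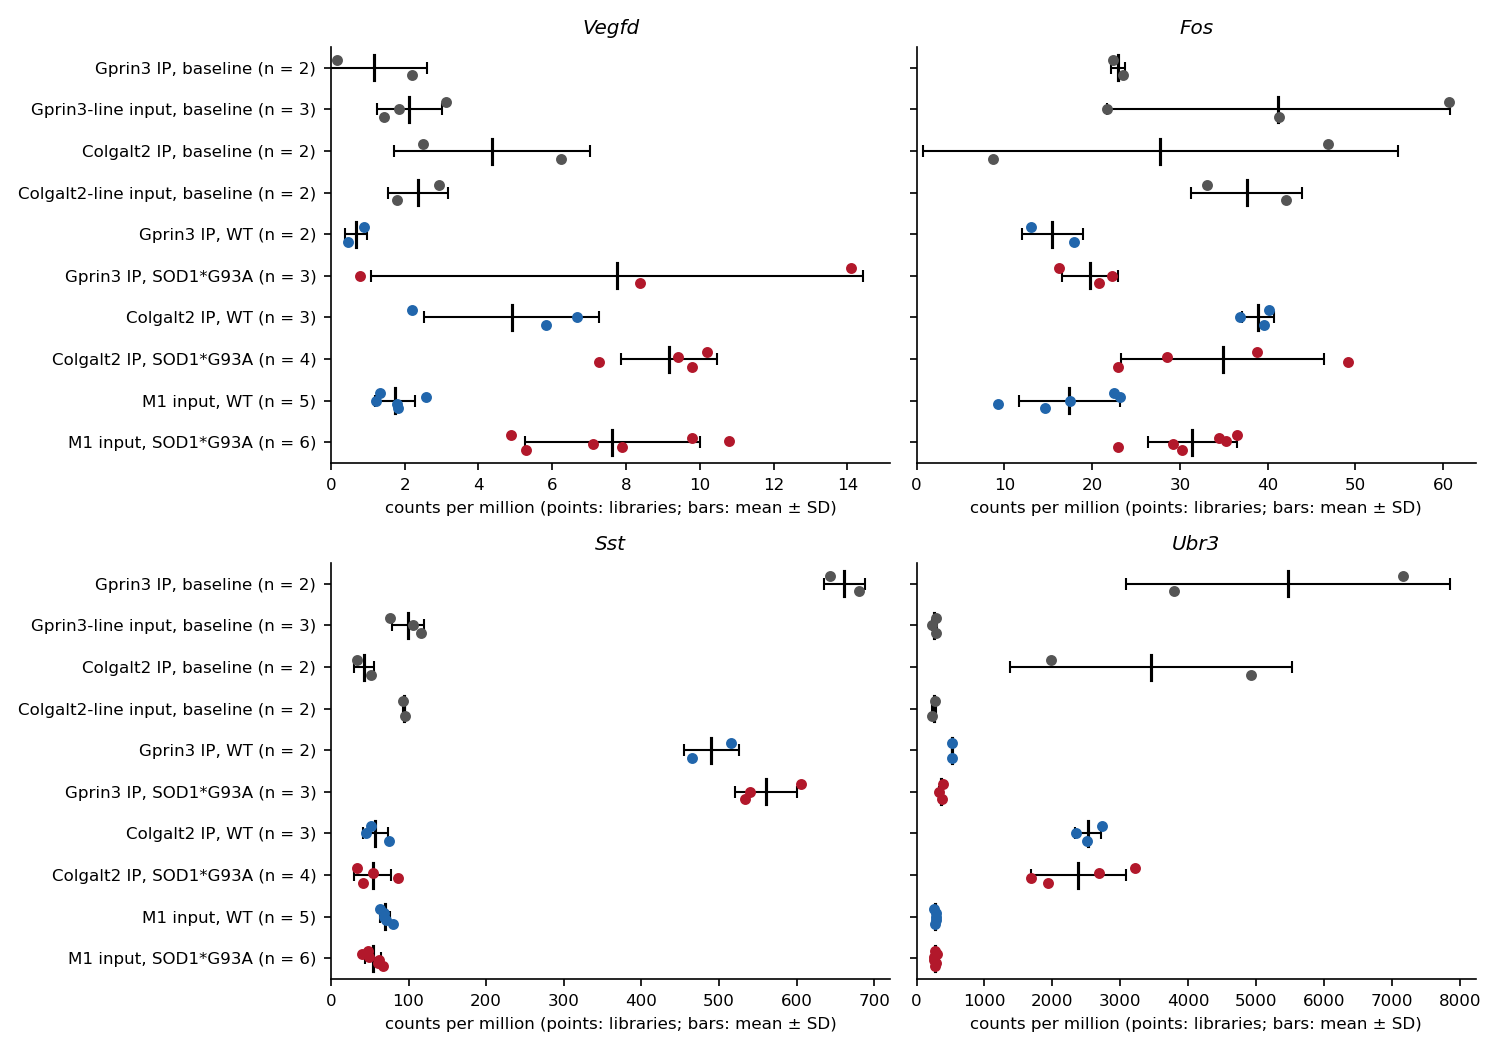
CPM of Vegfd, Fos, Sst and Ubr3 in each library (points) of the 10 groups, with group mean and SD as bars. Vegfd averages 7.62 CPM in SOD1*G93A and 1.74 CPM in WT M1 input, and Sst averages 661 CPM in baseline Gprin3 IPs against 42.3 CPM in Colgalt2 IPs.

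The SOD1*G93A effect was then compared between the IPs of both lines as an interaction over 12 libraries. Scube1, which encodes a secreted and membrane glycoprotein, fell more in Gprin3 IPs (35.5 ± 2.05 to 7.11 ± 1.25 CPM) than in Colgalt2 IPs (102 ± 8.01 to 86.2 ± 8.1 CPM), a log2 difference of effects of -2.06 ± 0.26 (adjusted p = 0.0017). It kept its call under every left-out library. Of 15483 genes tested 12 differed, all more negative in the Gprin3 line, among them Pclo (-1.67 ± 0.31), the stress-response gene Ndrg1 (-2.22 ± 0.41) and the calcium pump gene Atp2b4 (-1.63 ± 0.30), each with adjusted p = 0.0488. Oligodendrocyte (0 of 14 called over all genes, 10 lower over the list alone, median -2.07) and astrocyte markers (0 of 14, 7, median -1.77) were more negative in Gprin3 IPs (camera adjusted p = 3.4e-14 and 6.65e-08, and 0.169 and 0.26 with an estimated correlation). Axon guidance genes did likewise (0 of 67, 4 over the list alone, adjusted p = 4.3e-06, and 0.287 with an estimated correlation). The oxidative phosphorylation effect did not differ detectably between the lines (median difference 0.05, adjusted p = 0.14), and neither did that of Sod1 (0.54 ± 0.23, adjusted p = 0.468). Cytoplasmic ribosome (0 of 75, 0 over the list alone, median 0.07) and mitochondrial ribosome lists (0 of 77, 0, median 0.19) were called more positive in Gprin3 IPs (adjusted p = 0.0449 and 0.037, and 0.735 and 0.583 with an estimated correlation). The first of these calls was lost without Gprin3 WT IP 1 (0.105) or 2 (0.0764), Gprin3 SOD1*G93A IP 1 (0.161) or 2 (0.722), Colgalt2 WT IP 2 (0.0528) or 3 (0.131) or Colgalt2 SOD1*G93A IP 2 (0.0629) or 4 (0.248). The other was lost without Gprin3 WT IP 2 (0.13), Gprin3 SOD1*G93A IP 1 (0.287), Colgalt2 WT IP 3 (0.266) or Colgalt2 SOD1*G93A IP 2 (0.0685) or 4 (0.0761). Of the 17 lists called, 7 kept their call under each left-out library and 10 did not. The 7 were oligodendrocyte, astrocyte, axon guidance, oligodendrocyte precursor, microglia, disease-associated microglia and vascular genes, all more negative in Gprin3 IPs. The lines also differ here in tissue, M1 against whole cortex, so line and tissue cannot be told apart. Sex differs too, since Ddx3y was detected in all 7 Colgalt2 IPs, 3 of them with Xist at 138 CPM or more, and in 1 of the 5 Gprin3 IPs, all with Xist at 6.25 CPM or less. DESeq2 called 152 genes. The count was 146 without Colgalt2 WT IP 1, 21 without Gprin3 SOD1*G93A IP 2, 2 without Gprin3 WT IP 2, Gprin3 SOD1*G93A IP 1 or Colgalt2 SOD1*G93A IP 4, and 1 without Colgalt2 WT IP 2 or 3 or Colgalt2 SOD1*G93A IP 1 or 2. Scube1 was the gene left with the length trend taken out.

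Against the SOD1*G93A effect in M1 input, the effect in Gprin3 IPs differed in 2820 of 15503 genes over 16 libraries, 1051 more positive and 1769 more negative. Sod1 rose more in the IPs, by 0.88 ± 0.12 (adjusted p = 2.13e-05). Pclo and Bsn fell more in the IPs than in input, by -1.92 ± 0.13 and -2.23 ± 0.16 (adjusted p = 7.25e-10 and 3.26e-09), as did Dync1h1 (-2.33 ± 0.19) and Unc13a (-1.39 ± 0.14). Of 76 oxidative phosphorylation genes 59 were more positive in the IPs and 1 more negative (67 and 1 over the list alone, median 0.61, adjusted p = 2.54e-27, and 0.0539 with an estimated correlation). Cytoplasmic ribosome (37 of 75, 49 over the list alone) and mitochondrial ribosome genes (30 of 77, 37) were more positive too (adjusted p = 8.8e-19 and 7.96e-13, and 0.147 and 0.0571 with an estimated correlation). Oligodendrocyte (12 of 14, 12 over the list alone), astrocyte (11 of 14, 12) and oligodendrocyte precursor markers (6 of 9, 7) were more negative in the IPs (adjusted p = 5.07e-16, 4.15e-10 and 2.02e-07), Mbp by -1.57 ± 0.13. With an estimated correlation their adjusted p was 0.0245 each, and of the 125 camera calls over the 8 comparisons these 3 were the only ones to hold. They are glial lists in IPs of neurons, and the WT reference is 2 IPs with glial sums of 2220 to 3180 CPM. The sums were 1000 to 1010 CPM in SOD1*G93A and 1120 to 1140 CPM in baseline Gprin3 IPs. Whole-tissue RNA in the WT IPs thus cannot be told apart from an effect of genotype for these lists. With fry, which tests whether a set's genes move on balance one way and, in its mixed form, whether they change in either direction, neither of them against other genes, 77 calls were made. The count of genes was 1404 without Gprin3 WT IP 2 and 1768 with the length trend taken out.

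The authors' deposited DESeq2 tables, which cover the 6 pairwise comparisons, listed 4162, 3040, 4000 and 1901 genes at an adjusted p under 0.05 for Gprin3 IP over input, Colgalt2 IP over input, Gprin3 over Colgalt2 IP and SOD1*G93A over WT in Gprin3 IPs. They listed 120 for Colgalt2 IPs, 114 of them higher in SOD1*G93A, and 17 for M1 input. Genes called in both the deposited tables and here numbered 3786, 375, 907, 976, 0 and 15, all with the same sign. In M1 input, the deposited table gives Vegfd a log2 fold change of 2.17 ± 0.41 with an adjusted p of 1. Here it was 2.18 ± 0.24 with an adjusted p of 9.63e-06. The deposited adjusted p is hard to square with its own SE and may stand for a missing value. It therefore cannot be read as a lack of difference. In SOD1*G93A over WT Gprin3 IPs it gives Vegfd 3.56 with an adjusted p of 0.000181, against 3.5 here with an adjusted p of 0.0723. For Sod1 in Colgalt2 IPs it gives 0.64 with an adjusted p of 0.00662, against 0.65 here with an adjusted p of 0.387.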

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

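Among the tests below, those of whole-tissue RNA, of a few libraries behind Vegfd and of the Colgalt2 neighbour gene, and the corrections for length, GC content and sex, were chosen only after the result was seen.

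Genes changed by SOD1*G93A in Gprin3 IPs, 1118 in all, were weighed against transcript length, whole-tissue RNA in the WT IPs and genotype, and none of these could be told apart. With each library's length trend taken out, 34.6% of the called genes with a known length (384 of 1110) were still called in the same direction. The median absolute log2 fold change of the other 726 went from 0.79 to 0.42 with a median SE of 0.16 both times, so these calls ended through smaller folds. Of the called genes 73% (815 of 1117) moved as less whole-tissue RNA would move them. The glial sums of 2220 to 3180 CPM in WT against 1000 to 1010 in SOD1*G93A libraries go with that. Against it, 226 of 716 lower genes lay above input at baseline, but only 38 of them were called above it. Against the baseline WT IPs, 0.9% (10 of 1109) were called in the same direction and 66.1% kept their sign. That 66.1% cannot speak for genotype, since both comparisons share the SOD1*G93A libraries and the genes were picked on the littermate one. The baseline and littermate WT IPs differed from each other in 1837 genes, more than the 1118 between genotypes. Glial sums of the baseline IPs, 1120 to 1140 CPM, also lay nearer to those of SOD1*G93A. The calls thus depend on which WT reference is used. The baseline IPs were another set of samples, so genotype stays open too. Sod1, at 2.23-fold, is the change the genotype names in advance, but its 691 to 733 CPM in SOD1*G93A IPs lay within the 470 to 800 CPM of the baseline WT IPs. The reference is 2 WT libraries. Ddx3y was detected in 1 of them and in no SOD1*G93A IP, so sex stays open as well.

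Oxidative phosphorylation genes were higher in SOD1*G93A IPs of both lines, with a median log2 fold change of 0.57 in each. Of 10000 random lists matched on length and expression, the medians centred on 0.47 in Gprin3 IPs (central 95% up to 0.54), which put the list at percentile 99.61. In Colgalt2 IPs they centred on 0.31 (central 95% up to 0.39), percentile 100. Members of the random lists were drawn independently, which leaves out that genes of a list can vary together. These percentiles therefore cannot decide whether length is the whole cause. With the length trend taken out the median was 0.13 in Gprin3 and 0.16 in Colgalt2 IPs, so that trend may account for most of the rise in both lines. Whole-tissue RNA in the WT IPs stays a candidate explanation in the Gprin3 line, where the list lay 0.91 above input at baseline. In the Colgalt2 line the list lay at -0.04, below its rise in SOD1*G93A. The baseline Colgalt2 IPs behind that value had glial sums of 2180 to 3480 CPM themselves and came from M1. Their fold over input also ran with transcript length (Spearman 0.27), so the value cannot decide the question there. The Colgalt2 WT IP with the most Malat1 (3970 CPM) also had the highest glial sum (3480 CPM), and without it the median was 0.49. Xist was at 172 ± 176 CPM in WT and 35.8 ± 68.3 CPM in SOD1*G93A Colgalt2 IPs, so sex stays open there, as untested. Of the 35 splits of the 7 Colgalt2 libraries, 1, the real one, gave a median as far from 0 (0.57, highest other 0.46). That is the smallest share that 35 splits can give, and the list was singled out on the same libraries. The splits thus cannot exclude chance for that list. That SOD1*G93A raised these genes in Colgalt2 neurons is left as a hypothesis, found and tested on the same data and not past an estimated correlation.

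Vegfd was higher in SOD1*G93A M1 input, and the tables argue against sex, a few SOD1*G93A libraries and GC content as the whole cause. With sex as a covariate its log2 fold change was 2.12, against 2.18 without, and with the GC trend taken out 2.15. Without the 3 SOD1*G93A libraries highest in Vegfd it was 1.77 ± 0.29 (adjusted p = 0.00995). A rise with genotype may then be proposed as a hypothesis, since litter and age within the range were not tested.

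For the count of genes in M1 input, 1 of 100 drawn splits of the 462 possible, the real one, gave as many (482, highest other 27), which argues against chance for that count. For the immediate early list's median it was likewise 1 of 100 (0.45), but another drawn split reached 0.42. That list was singled out on the same libraries, so the splits do not exclude chance for it. For Colgalt2 IPs the real count was 0 genes by edgeR (1072 at an unadjusted p under 0.05, 74 by DESeq2), which all 35 splits reach by construction, so they say nothing about chance there. Of the other splits 32 also gave 0 genes and the highest gave 118, which may point to a structure among these 7 samples other than genotype, a reading that was not tested further.

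Single libraries stood apart from the rest of their group in 4 of 27 tests, where chance alone gives about 1 in 20 groups, or 1.4. Malat1 was at 2360 CPM in Colgalt2 SOD1*G93A IP 2, against 361 to 536 in the others. Gprin3 was at 23.5 CPM in the same library, against 33.7 to 35.2. The total of SOD1*G93A input 2 was 48.1 M counts, against 16.1 to 27.4 M. Rpl10a was at 21 CPM in SOD1*G93A input 6, against 11.4 to 14.2. The SOD1*G93A effect differed between Gprin3 and Colgalt2 IPs in 12 genes and between Gprin3 IP and M1 input in 2820 genes, by the interaction tests in the report. Colgalt2 was at 54.9 CPM in inputs of the Colgalt2 line against 4.2 CPM in inputs of the Gprin3 line, a pair of groups that none of the 8 tested comparisons covers.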

How the results depend on the processing

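The length, GC, purity and sex corrections and the baseline WT reference were chosen only after the data were seen. Counts rested on few libraries: where 1 was left out of a pair, the lone sample was assumed to vary like the other groups. With each library left out, the count ran from 2284 to 5931 for Gprin3 IP over input, 1 to 7206 for Colgalt2 IP over input, 137 to 1705 for Gprin3 over Colgalt2 IP, 141 to 1653 for SOD1*G93A in Gprin3 IPs, 0 to 6 in Colgalt2 IPs, 180 to 471 in M1 input, 1 to 146 for the interaction between lines and 1404 to 3451 for that between IP and input. The cause of these shifts was not tested. Replicate numbers did not pair samples (same-number correlations of residuals between -0.08 and 0.07), and as a block they gave 1502 genes for Colgalt2 IP over input, 1749 for SOD1*G93A in Gprin3 IPs and 1 for the interaction between lines.

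With no low-count filter the counts were 1741 for Colgalt2 IP over input, 1558 for Gprin3 over Colgalt2 IP, 1720 for SOD1*G93A in Gprin3 IPs and 51 for the interaction between lines, and with the stricter filter 639 for Colgalt2 IP over input and 1 for that interaction. DESeq2 gave 1871, 1550, 2015, 74, 907 and 152 genes for Colgalt2 IP over input, Gprin3 over Colgalt2 IP, SOD1*G93A in Gprin3 IPs, Colgalt2 IPs and M1 input, and the interaction between lines. Joint fits gave 2311 and 3272 for the first pair of these, 12 for Colgalt2 IPs and 41 for M1 input, and RLE factors gave 1 for the interaction between lines. Taking out the length trend left 0 genes by edgeR for Colgalt2 IP over input (378 without it, 3595 at an unadjusted p under 0.05), 307 for Gprin3 over Colgalt2 IP, 531 for SOD1*G93A in Gprin3 IPs, and 1 and 1768 for the interactions. Taking out the GC trend left 83 for Colgalt2 IP over input, 262 for M1 input and 1 for the interaction between lines. The WT littermate IPs gave 1927 between lines, and the baseline IPs as reference 64 for SOD1*G93A in Gprin3 IPs. Against the 125 list calls of camera, camera with an estimated correlation made 3 and fry 77. Fry lost 70 of the 125 and added 22 that camera had not made.

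Directions turned in 5 cases: with the length trend out, Pclo between lines at baseline (0.01), Grin2b in SOD1*G93A Gprin3 IPs (0.19) and B2m between IP and input effects (-0.02), and with a library left out, Ndufa4l2 between IP and input effects (0.04 without Gprin3 WT IP 1, lowest fitted value -8.46 without Gprin3 WT IP 2) and the sex chromosome list between lines (adjusted p = 0.553 without Gprin3 WT IP 2, lowest 1.14e-33 without Gprin3 WT IP 1). Of the named genes' results, 407 kept their direction and side of the threshold, called or not, with the length trend out and 150 lost the call, and with each library left out 3702 kept both, 791 lost and 30 gained the call. Of the list results, 223 kept direction and side, called or not, and 27 lost the call with the length trend out, and 1902 and 133 did so with each library left out.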

Other observations

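The levels below were picked after their values were seen, and the test of the neighbour gene was chosen only after the result was seen.

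Somatostatin and parvalbumin transcripts were above input in every group of Gprin3 IPs, but those of Vip and Npy, neuropeptides of other interneurons, were not. Sst was at 661 ± 26.3 CPM at baseline, 490 ± 35 CPM in WT and 560 ± 40 CPM in SOD1*G93A Gprin3 IPs, against 42.3 to 57.4 CPM in the 3 groups of Colgalt2 IPs and 54.6 to 99.3 CPM in inputs. Pvalb, a calcium buffer gene of fast-spiking interneurons, was at 188, 213 and 257 CPM in Gprin3 IPs at 18.3 to 51.9 CPM in Colgalt2 IPs and at 86.6 to 98.8 CPM in inputs. Vip was at 10.7 to 15.6 CPM and Npy at 53.6 to 71.7 CPM in Gprin3 IPs, against 26.9 to 37.1 and 83.4 to 140 CPM in inputs. Gad1 at baseline was at 118 CPM in Gprin3 IPs and 129 CPM in their inputs, although the interneuron list was called higher there (camera adjusted p = 0.000679, and 0.137 with an estimated correlation). No difference between SOD1*G93A and WT was called for Sst in Gprin3 IPs (log2 fold change 0.19 ± 0.12, adjusted p = 0.391).

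Ubr3, Atg7 and Yeats2 were far above input in baseline IPs of both lines and in Colgalt2 IPs of the second set, but not in Gprin3 IPs of that set. Ubr3 was at 5480 and 3450 CPM in the baseline Gprin3 and Colgalt2 IPs and 2530 and 2380 CPM in WT and SOD1*G93A Colgalt2 IPs, against 521 and 365 CPM in WT and SOD1*G93A Gprin3 IPs and 255 to 275 CPM in inputs. Atg7 followed it, with 428, 235, 415 and 400 CPM in the first 4 of these groups and 40.3 and 42.7 CPM in the others. Not all of the largest rises at baseline followed this pattern. Kalrn stayed above input, at 1800 ± 192 and 3190 ± 1090 CPM in WT and SOD1*G93A Gprin3 IPs against 583 and 546 CPM in WT and SOD1*G93A inputs. Cdr1, a brain-enriched gene, was at 223 to 450 CPM in all IPs and 2940 to 4400 CPM in inputs. Vegfd, raised in SOD1*G93A M1 input, was at 7.75 ± 6.67 against 0.685 ± 0.295 CPM in Gprin3 IPs (adjusted p = 0.0723) and 9.17 ± 1.31 against 4.9 ± 2.37 CPM in Colgalt2 IPs (adjusted p = 0.639), neither past the threshold. The authors' deposited table gives Vegfd in Gprin3 IPs a log2 fold change of 3.56 with an adjusted p of 0.000181.

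Between the inputs of both lines at baseline, 3 genes were higher in the Colgalt2 line and 4 lower, of 14891 tested with edgeR. Colgalt2 was higher by 3.69 ± 0.19 on the log2 scale (12.9-fold), and Tsen15, whose transcription start is the nearest to it at 13142 bp, by 3.19 ± 0.14, in both Colgalt2-line inputs over all 3 others. Rgl1 on the other side, which ends nearer to Colgalt2 at 6065 bp but starts 255656 bp away, differed by 0.08 ± 0.14. Extra copies of the locus on the bacTRAP transgene may therefore raise both genes in whole tissue, a hypothesis that the value of 3.19 fits and that was formed on these data. If that hypothesis holds, the high Colgalt2 level in Colgalt2 IPs is not an independent check of the purified cells.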
